A study of Arabidopsis thaliana with 32 samples.

How the data were processed

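Roots of Arabidopsis thaliana seedlings were profiled by RNA sequencing in 8 groups of 4 samples, 32 samples in all. The groups cross genotype (wild-type Col-0 or Sku6), age (4 or 8 days) and place of growth (spaceflight or ground). Per the labels' protocols, seedlings grew in the Veggie hardware on the International Space Station under 100 to 135 µmol of photosynthetically active light, and the ground set followed with a delay of 48 h. Per the same protocols, roots were dissected from seedlings fixed in RNAlater, and each replicate pooled 5 to 8 roots at 4 days or 2 to 3 roots at 8 days. Libraries were made from 10 ng of RNA with the SMART-Seq v4 kit and Nextera tagmentation, per the labels' protocols. The samples of a group are therefore separate pools of roots.

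The authors processed the reads before deposit. Per the submitters' processing notes, the tools included Trimmomatic 0.36, FastQC 0.11.2, STAR 2.5.1b, Picard, Cufflinks and Cuffdiff, and the genome build was TAIR10. The order and settings of these steps are not given in the sources used here. The authors deposited 12 tables, each for 1 comparison of 2 groups. Each table gives a group value in FPKM (fragments scaled to transcript length and to the number of mapped fragments), the log2 fold change of the groups, a p-value and a q-value, per the file headers. The deposited FPKM values belong to whole groups, so no value per sample, no spread between replicates and no sequencing depth was in hand. The deposited tables hold only loci with a q-value of at most 0.05, 12215 entries over 4802 loci. A locus without an entry is called not listed here, which does not show that it was unchanged. The authors' smallest p-value was 5e-05 in every table, so many loci share the lowest q-value of a table.

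The tables were scaled separately. The value of 1 group differed between tables by a factor of up to 1.04 over 4143 values that could be compared, so levels taken from different tables carry that difference. Fold changes were given as flight over ground, 8 days over 4 days and Sku6 over Col-0, and the deposited log2 values were used with the sign set to these directions. A fold change was not given where a group was listed at 0. The deposited test statistic was not used. The number of loci the authors tested was worked back from the p- and q-values of each table.

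A locus counted as changed where the authors' q-value was at most 0.05, with no test added, because no values per sample were in hand. The overlap of 2 tables was counted per direction and tested with Fisher's exact test (1-sided, for more shared loci), with the 4802 loci listed in any table as background and Benjamini-Hochberg adjustment over the 12 pairs. No pair of tables compared in this way shared a sample. For 18 gene lists, the changed members were counted and tested with Fisher's exact test (2-sided) against the 5063 gene identifiers listed in any table. An exact 2-sided sign test compared members that were higher with members that were lower, taking the 2 directions as equally likely. Both tests were adjusted over 216 tests. In the sign test, 10 of 10 members on 1 side gave an adjusted p of 0.0703. No list with 10 or fewer changed members could therefore pass it. The design, these lists, the rule for named genes and the first group of alternatives below were fixed before the data were examined. The lists covered microtubules and SPIRAL genes, wall loosening, root hairs, heat shock, hypoxia, defence, jasmonate with wounding and touch, auxin, photosynthesis (also a marker of shoot tissue), seed storage (also a marker of seed remains), the cell cycle, xylem and secondary wall, endodermis and suberin, phosphate starvation, iron, nitrate and sulfur, abscisic acid with cold and dehydration, and the circadian clock. The count adjusted over the list alone was not computed, since p-values of members that are not listed were not in hand. Another 3 lists (salicylate and systemic resistance, low energy, light and flavonoids) were written after results had been seen and were tested in 36 tests of their own. Genes are not independent replicates, so the p-values of overlaps and lists describe these tables and not a population of plants.

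Named genes followed a fixed rule. Per comparison, it took the 6 genes with the highest and the 6 with the lowest fold change among changed genes that reached 5 FPKM in a group, leaving out loci that merge several genes and values of 0. It added up to 4 members of each list with at least 3 changed members, SPR1 and its relatives in the genotype comparisons, and for each overlap the 4 genes with the strongest change in the same direction and the 4 in opposite directions. Genes named outside this rule are said to be so where they appear.

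Of the 5063 identifiers, 5040 had an entry in the TAIR10.1 annotation, from which gene names were taken. All 11429 entries for a single annotated gene overlapped that gene. The files count start positions from 0, and 1 was added. A merged locus, of which there were 295, carries several gene identifiers with a shared value, so the value cannot be assigned to 1 of them, and 44 loci carried no identifier. Because reads were not counted here, values of near-identical family members, such as the small subunit genes of Rubisco, depend on how the authors' tools divided shared reads.

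The alternatives were a q-value of 0.01, a minimum absolute log2 fold change of 1, 1 FPKM added to both groups, minimum values of 1 or 5 FPKM, exclusion of values of 0, and the protein-coding genes of the reference as background. Chosen after seeing the data were a background of the number of loci tested and the exclusion of merged loci or loci without an identifier. The overlap test, the list tests and the number of loci worked back were tried on simulated data. Calls there were made at p under 0.05 without adjustment. In 200 simulations of the 12 pairs, independent lists drawn from the 4802 loci were called in 0.5 to 7% of runs per pair and planted overlaps in 100%. All loci were drawn with equal probability there. Overlap that arises because some loci are easier to call in every comparison was therefore not simulated, and the overlap tests do not allow for it. In 200 simulations of the 12 comparisons on the 5063 identifiers, lists with no planted change were called in at most 3.5% of runs. Lists with at least 10 of 25 members changed were called in 50.5 to 100%, depending on the comparison. The fixed lists had 0 to 19 members in the background and were called after adjustment, so these rates do not carry over to them. Calculations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.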

Results

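Root transcripts were measured by RNA sequencing in wild-type Arabidopsis of the Col-0 accession and in Sku6, a line with the sku6 allele of SPIRAL1. SPIRAL1 is a microtubule-associated protein whose loss makes root growth skew. Seedlings of both genotypes grew on the International Space Station or on the ground and were sampled at 4 and 8 days, with 4 samples in each of the 8 groups. The authors' deposited tables give 1 FPKM value per group and list only loci called at their q-value threshold of 0.05, so the values below have no spread between replicates and the depth is unknown. The q-values are the authors' own, computed over 19464 to 20035 loci per comparison as worked back from the tables. Fold changes of genes with a group under 2 FPKM can depend on that low value, and those that shrank by more than 1.5 times with 1 FPKM added are named in the part on processing.

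**Figure D1:**
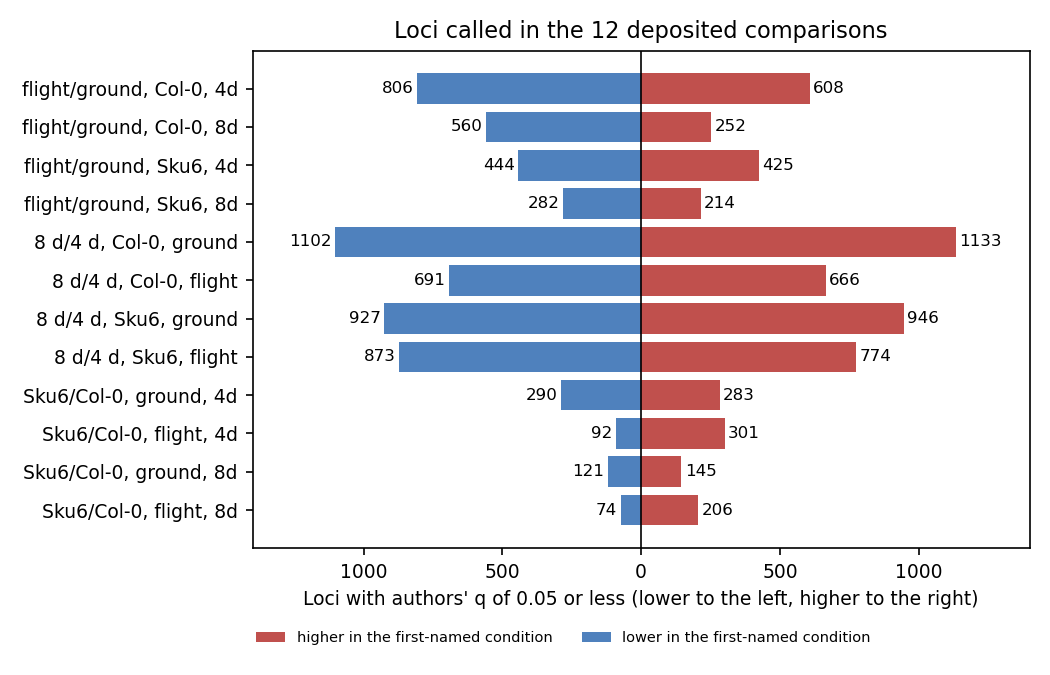
Number of loci called in each of the 12 comparisons of the authors' deposited tables, with loci higher in the first-named condition to the right (red) and lower loci to the left (blue). The comparison of 8 with 4 days in ground Col-0 has the most calls, 2235, and Sku6 against Col-0 on the ground at 8 days the fewest, 266.

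The gene altered in Sku6 was examined first. SPR1 (AT2G03680; TAIR10.1 chromosome 2, 1120787 to 1122055) lies within a locus that the files place at 1100339 to 1133656 on chromosome 2. In the authors' deposited tables its level in Sku6 was 7.21 FPKM against 1262 in Col-0 on the ground at 4 days and 8.13 against 1210 in flight at 4 days. At 8 days the deposited levels were 13 against 1422 on the ground and 10.1 against 1269 in flight. The deposited log2 fold changes were −7.45, −7.22, −6.78 and −6.97 in that order, with q-values of 0.00409, 0.00499, 0.00610 and 0.00750. Each Sku6 group thus held under 1% of the SPR1 level of its Col-0 partner, as its label says. No other SPIRAL1-like gene was listed in a genotype comparison.

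Spaceflight was compared with ground growth in each genotype and age to find which root transcripts differ between flight and ground roots. The samples of a group are separate pools of roots, and the ground set followed the flight set by 48 h. Effects of spaceflight therefore cannot be told apart from other differences between the flight and ground sets, such as the time of the run or handling. In Col-0 roots of 4 days, the strongest rises in the authors' deposited table were in SEN1 (AT4G35770), a gene induced in darkness, at 18 FPKM in flight against 1.19, and in the peroxidase gene AT1G49570 at 9.65 against 0.658. The microRNA precursor MIR864 rose 13.3-fold, bZIP1 (AT5G49450), a transcription factor of low-energy signalling, 7.90-fold, the stress gene OXS3 (AT5G56550) 6.98-fold and the kelch-repeat gene KFB20 (AT1G80440) 5.90-fold in the authors' deposited table. Lower in flight were BBX30 (AT4G15248), a small B-box protein gene, at 4.75 against 31.2 FPKM, and the early light-induced genes ELIP1 (AT3G22840) at 18 against 97.4 and ELIP2 (AT4G14690) at 29.3 against 130, by the authors' deposited table. The dirigent-like gene AT2G39430, AT4G18422 of unknown function and the peroxidase gene AT5G66390 were also among the strongest decreases, with deposited log2 values of −2.31, −2.23 and −2.16 in the authors' deposited table.

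Of the endodermis and suberin list, 9 members were lower in 4-day Col-0 flight roots and none was higher, where 3.24 changed members were expected (Fisher's exact test, adjusted p = 0.00970). In the authors' deposited table the fatty acid hydroxylase genes of suberin synthesis, CYP86B1 and CYP86A1, had log2 values of −1.55 and −1.41, the feruloyl transferase gene ASFT −1.37, and ESB1, a dirigent protein gene of the Casparian strip, was 2.47-fold lower. Lignin laccase genes LAC17 and LAC4 were at 3.58 against 9.72 and 10.1 against 18.6 FPKM in the authors' deposited table, within 4 xylem list members that were all lower. The 4 changed nitrate and sulfur genes were lower too, among them nitrate reductase NIA1 at 12 against 27.3 FPKM and the sulfate assimilation genes APR1 and APR2 at 40.8 against 77.3 and 42.7 against 79.1 in the authors' deposited table. Wall-loosening genes included 1 higher (XTH26, 21.0 against 10.7 FPKM) and 7 lower members such as EXPB3 (221 against 353), by the authors' deposited table. Auxin genes LBD29, GH3.2 (a merged locus) and LAX3 were lower, with deposited log2 values of −1.24, −1.11 and −0.68 in the authors' deposited table. The hypoxia list split into 3 higher and 3 lower members, and the 6 changed photosynthesis genes were all lower, against 5.6 expected. No list except suberin passed a test here. The xylem list and the nitrate and sulfur list each had 4 changed members against 2.36 expected (Fisher's exact test, adjusted p = 0.689 for each). Wall loosening had 8 against 5.6 (Fisher's exact test, adjusted p = 0.648). In all, 1414 loci were called, 608 higher and 806 lower in flight, and 276 of them changed at least 2-fold, 102 of these higher.

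In Col-0 roots of 8 days, genes of the light-harvesting apparatus were lower in flight. All 13 changed members of the photosynthesis list were lower, against 3.2 expected (Fisher's exact test, adjusted p = 4.32e-05; exact sign test, adjusted p = 0.0264). The sign test takes both directions as equally likely, but 560 of the 812 loci called in this comparison were lower. Its p-value thus partly reflects that skew. The antenna genes LHCB2.2 and LHCB2.1 stood at 0.634 against 3.43 and 3.02 against 13.6 FPKM, LHCB1.3 at 80.1 against 169 and LHCB6 at 21.1 against 43.4, by the authors' deposited table. With 1 FPKM added to both groups, the log2 value of LHCB2.2 went from −2.43 in the authors' deposited table to −1.44. The direction of the list no longer passed with a minimum log2 fold change of 1, which left 4 members, all lower and too few to pass (exact sign test, adjusted p = 1). The list also marks shoot tissue on a dissected root. Among the comparisons of 8-day groups, 13 members were called here and 9 for Sku6 against Col-0 on the ground. In the 2 comparisons without ground Col-0, 0 were called. The list of abscisic acid, cold and dehydration genes had 6 lower members and none higher, against 1.18 expected (Fisher's exact test, adjusted p = 0.00322). The cold-induced gene KIN1 (AT5G15960) was at 64.8 against 248 FPKM, RD29A at 1.94 against 3.70 and the dehydrin gene XERO2 at 167 against 282 in the authors' deposited table. This call did not hold with a minimum log2 fold change of 1, which left KIN1 as the changed member (Fisher's exact test, adjusted p = 0.603).

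The strongest rises in 8-day Col-0 were in AT5G55620 of unknown function at 5.61 against 0.798 FPKM and in the cytokinin response regulator gene RR17 (AT3G56380) at 6.78 against 1.14 in the authors' deposited table. MIR158b and MIR160b rose 5.24-fold and 3.54-fold, AT2G04460 4.17-fold and the phosphoglycerate mutase-like gene AT5G04120 3.15-fold in the authors' deposited table. The F-box gene AT1G73120, BBX30, AT1G12805 and BBX31 (AT3G21890) were lower, with log2 values of −2.68, −2.22, −1.84 and −1.80 in the authors' deposited table. All 8 changed hypoxia genes were lower, short of the threshold for the list (Fisher's exact test, adjusted p = 0.0685). Among them were the fermentation genes PDC1 (pyruvate decarboxylase) and ADH1 (alcohol dehydrogenase) at 5.22 against 16.8 and 14.7 against 38.4 FPKM in the authors' deposited table. Of the 5 changed suberin genes all were lower, such as FAR5 at 32.2 against 52.3 FPKM, and of 6 changed phosphate starvation genes 5 were higher, such as SPX1 at 49.1 against 32.7, by the authors' deposited table. Neither list passed (Fisher's exact test, adjusted p = 0.156 and 0.0685), nor did the clock and jasmonate lists. The clock genes PRR9, LUX and LHY were lower, PRR9 at 0.411 against 2.22 FPKM in the authors' deposited table. The jasmonate list held 3 higher and 2 lower members, with JAZ7 at 7.85 against 2.54 FPKM in the authors' deposited table. There were 812 calls, 252 higher and 560 lower, of which 103 reached 2-fold, 51 of these higher.

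In Sku6 roots of 4 days, SEN1, OXS3 and bZIP1 were again higher in flight, at 16.4 against 1.16, 88.1 against 5.34 and 37.9 against 2.96 FPKM in the authors' deposited table. The germin-like gene AT5G38940 rose 17.0-fold, the glycine-rich protein gene AT2G05510 16.1-fold, the F-box gene AT3G23880 13.5-fold and BT2 (AT3G48360), a BTB and TAZ domain gene that responds to sugar and nitrogen supply, 12.9-fold in the authors' deposited table. BBX30 and ELIP1 were lower at 4.40 against 54.2 and 10.2 against 123 FPKM in the authors' deposited table. AT4G18422 and the snoRNA AT4G02555 had log2 values of −3.02 each, and the annexin gene ANNAT7 (AT5G10230) and marneral synthase MRN1 (AT5G42600) −2.83 each, in the authors' deposited table. Changed hypoxia genes were all higher (6 of 6), such as ARD3 at 7.35 against 1.70 FPKM, and changed suberin genes all lower (5 of 5), such as ASFT at 23.0 against 91.2, by the authors' deposited table. No fixed list passed its test in this comparison.

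The sulfur gene LSU2 (a merged locus), NIA1, APR1 and APR2 were lower in 4-day Sku6 flight roots, with log2 values of −1.67, −1.53, −1.28 and −1.06 in the authors' deposited table. In the iron list 4 members were higher and 1 lower, among them the regulators BHLH100 at 10.6 against 3.36 and BHLH101 at 5.13 against 1.82 FPKM, by the authors' deposited table. The Rubisco small subunit genes RBCS2B, RBCS1B and RBCS3B, markers of shoot tissue, were higher at 34.2 against 12.8, 37.3 against 18 and 74.8 against 39.1 FPKM, while LHCB2.1 was lower at 5.83 against 12.7, by the authors' deposited table. The clock gene GI was at 7.79 against 16.9 FPKM, RVE1 at 5.40 against 2.61, and the touch-induced gene TCH3 at 31.8 against 10.5 in the authors' deposited table. Of 869 calls, 425 were higher and 444 lower. At least 2-fold changes made up 367 of them, and of these 215 were higher.

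In Sku6 roots of 8 days, the oxygen-responsive genes of the hypoxia list changed with flight more often than expected. The list had 7 higher members and none lower, against 1.96 expected (Fisher's exact test, adjusted p = 0.0285), and its direction did not pass (exact sign test, adjusted p = 0.153). The desaturase gene SAD6 stood at 15.8 against 4.65 FPKM, HUP36 at 35.4 against 16.0, ADH1 at 26.5 against 12.2 and the oxygen-sensing cysteine oxidase gene PCO2 (a merged locus) at 18.5 against 9.71, by the authors' deposited table. This call was lost with merged loci left out (Fisher's exact test, adjusted p = 0.0507) and with a minimum log2 fold change of 1 (Fisher's exact test, adjusted p = 0.0873). The 7 changed suberin genes, against 1.13 expected (Fisher's exact test, adjusted p = 0.000977), and the 6 changed genes of the abscisic acid, cold and dehydration list, against 0.722 expected (Fisher's exact test, adjusted p = 0.000323), were all lower. Neither held with a minimum log2 fold change of 1, which left 0 and 1 changed members. In the authors' deposited table the suberin genes GPAT5 and CYP86B1 were at 7.29 against 12.6 and 9.37 against 15.1 FPKM, and KIN1 at 81.7 against 351.

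The strongest rise in 8-day Sku6 was in AT4G33720, a pathogenesis-related protein family gene, at 103 against 7.59 FPKM, followed by AT1G49570 at 8.70 against 1.01 and MIR864 at 10.5 against 1.35, by the authors' deposited table. The AP2-type transcription factor gene AT5G61590 rose 5.16-fold, bZIP1 4.14-fold and OXS3 4.13-fold in the authors' deposited table. MIR160b had the lowest log2 value, −2.74, followed by the MYB-like gene EPR1 (AT1G18330, −2.56), ELIP1 (−2.52), the flowering regulator CDF3 (AT3G47500, −2.18), KIN1 (−2.10) and BBX30 (−2.04) in the authors' deposited table. The clock genes LUX, GI and LHY were lower, with LUX at 23.7 against 49.9 FPKM in the authors' deposited table. XTH26 was higher at 20.4 against 7.97 FPKM, and EXPA8 and XTH9 lower at 3.25 against 6.59 and 264 against 402, by the authors' deposited table. In total 496 loci were called, 214 higher and 282 lower, with 111 at 2-fold or more, 65 of these higher.

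The responses of the 2 genotypes to flight were set side by side. At 4 days, 438 loci were called in both, 430 of them in the same direction, 3.35 times the 128 expected of independent lists from the 4802 listed loci (Fisher's exact test, adjusted p = 5.09e-30 for higher and 4.35e-133 for lower loci). SEN1, AT1G49570, bZIP1 and OXS3 led the shared changes, with log2 values in Col-0 and Sku6 of 3.93 and 3.82, 3.87 and 3.31, 2.98 and 3.68, and 2.80 and 4.04 in the authors' deposited tables. At 8 days, 201 loci were shared and 187 had the same direction, 4.24 times the 44.1 expected (Fisher's exact test, adjusted p = 2.35e-17 for higher and 1.14e-61 for lower loci). Here AT1G49570 (2.17 and 3.1), BBX30 (−2.22 and −2.04), KIN1 (−1.94 and −2.10) and BBX31 (−1.80 and −1.90) led on the log2 scale of the authors' deposited tables. Opposite directions were found for 8 loci at 4 days and 14 at 8 days.

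**Figure D2:**
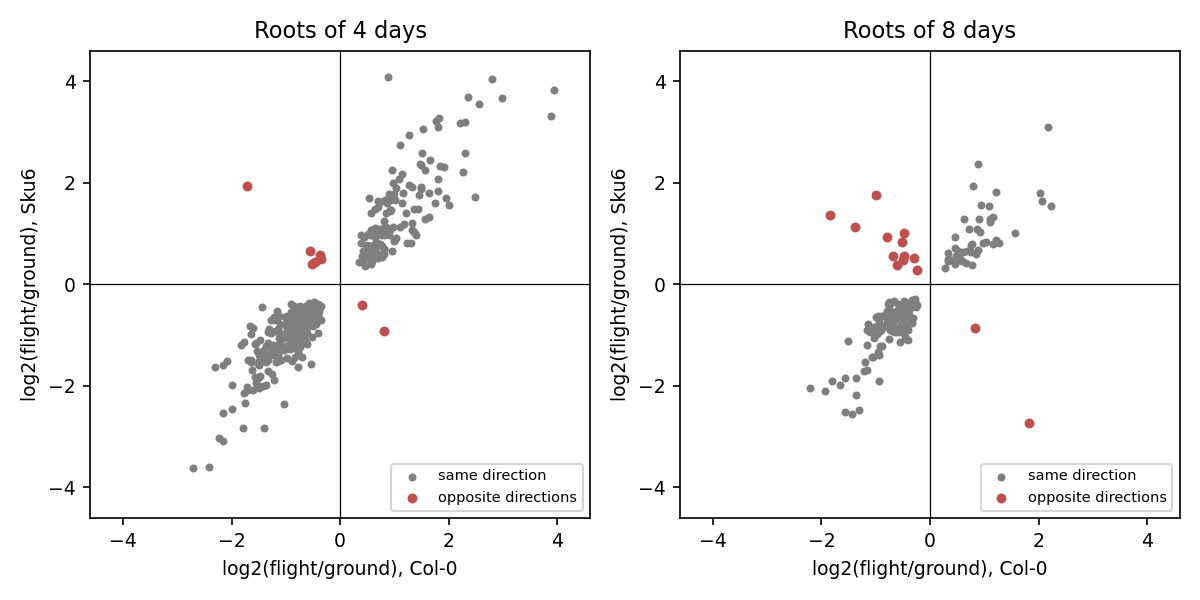
Log2 ratio of flight to ground in Col-0 (horizontal axis) and Sku6 (vertical axis) for each locus called in both genotypes in the authors' deposited tables, at 4 days (left) and 8 days (right). Grey points (same direction) number 430 and 187, and red points (opposite directions) 8 and 14.

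Between ages, the flight responses of Col-0 at 4 and 8 days shared 319 loci, 303 with the same direction and 2.41 times the number expected (Fisher's exact test, adjusted p = 1.58e-18 for higher and 5.49e-42 for lower loci). The flight responses of Sku6 at the 2 ages shared 250 loci, 245 with the same direction and 5.44 times the number expected (Fisher's exact test, adjusted p = 3.08e-61 for higher and 5.57e-71 for lower loci). In Col-0 these included BBX30 (log2 of −2.72 at 4 and −2.22 at 8 days), AT1G49570 (3.87 and 2.17), MIR160b (2.49 and 1.82) and BBX31 (−1.75 and −1.80) in the authors' deposited tables. In Sku6 AT1G49570 (3.31 and 3.1), EPR1 (−2.55 and −2.56), ELIP1 (−3.59 and −2.52) and AT5G61590 (3.18 and 2.37) led on the log2 scale of the authors' deposited tables.

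Roots of 8 days were compared with roots of 4 days to follow development in each place and genotype. In ground Col-0, VSP2 (AT5G24770), a vegetative storage protein gene induced by jasmonate, rose from 1.18 to 73.6 FPKM and DIR1 (AT5G48485), a lipid transfer protein gene of systemic resistance, from 2.89 to 175 in the authors' deposited table. The MADS-box gene AGL14 (AT4G11880) rose 21.0-fold, the oxygenase gene AT1G52820 19.4-fold, AT4G33720 18.6-fold and the zinc finger gene AT2G26695 15.0-fold in the authors' deposited table. AT2G04460 fell from 37.0 to 1.28 FPKM, ECS1 (AT1G31580) from 11.8 to 0.598, RBCS2B from 11.4 to 0.636, the cytochrome P450 gene AT3G44970 from 9.48 to 0.543, MLP168 from 9.45 to 0.793 and RBCS1B from 13.4 to 1.27 in the authors' deposited table. The wall-loosening list changed more than expected, with 5 higher and 10 lower members against 8.75 expected (Fisher's exact test, adjusted p = 0.0490). XTH9 rose from 95.9 to 344 FPKM and EXPA10 from 2.62 to 5.76, while XTH16 fell from 54.3 to 23.8 and XTH12 from 23.9 to 11.1, by the authors' deposited table. That call was lost with merged loci left out (Fisher's exact test, adjusted p = 0.0590) and with a minimum log2 fold change of 1 (Fisher's exact test, adjusted p = 0.109).

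The other lists in ground Col-0 passed neither test. Phosphate starvation genes were lower in 10 of 10 changed members, with the non-coding RNA IPS1 falling from 95.8 to 24.8 FPKM and the transporter PHT1;4 from 39.8 to 9.87 in the authors' deposited table. Root hair genes were lower in 9 of 9, including PRP3 (160 to 74.7 FPKM) and RSL2 (11.2 to 6.61), and auxin genes in 6 of 8, including GH3.1 (1.95 to 0.647) and GH3.5 (20.4 to 7.48), by the authors' deposited table. Hypoxia genes were higher in 11 of 13, with ADH1 rising from 4.69 to 37.1 and HB1, a haemoglobin gene, from 40.1 to 139 FPKM in the authors' deposited table. Jasmonate genes were higher in 6 of 6, with VSP1 rising from 6.70 to 86.3 FPKM in the authors' deposited table. Iron genes were lower in 8 of 10, for example NAS2 from 67.9 to 30.0 FPKM, and nitrate and sulfur genes in 5 of 5, for example the nitrate transporter NRT2.1 from 4.38 to 0.662, by the authors' deposited table. Heat shock genes (3 higher, 2 lower) included GolS1, up from 7.46 to 45.1 FPKM, and microtubule genes (1 higher, 3 lower) included SP1L5, up from 78.2 to 203, by the authors' deposited table. The defence list had 3 lower members, such as the camalexin gene PAD3 (17.5 to 8.89 FPKM), in the authors' deposited table. Calls numbered 2235, 1133 higher and 1102 lower, and of the 578 at 2-fold or more 353 were higher.

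In flight Col-0 the same age comparison again raised DIR1 (1.91 to 93.9 FPKM), VSP2 (1.65 to 43.7), AT4G33720 (2.93 to 60.5) and AT1G52820 (4.18 to 62.3) in the authors' deposited table. The beta-glucosidase gene BGLU7 (AT3G62740) rose 25.5-fold and XTH7 (AT4G37800) 12.4-fold in the authors' deposited table. ECS1, the F-box gene AT1G73120, SEN1, AT1G09310, the lipid transfer gene LTP (AT2G15050) and RBCS1B were lower, with log2 values of −4.16, −3.90, −3.65, −3.62, −3.56 and −3.48 in the authors' deposited table. The hypoxia list changed more than expected (9 higher, 3 lower, 5.37 expected; Fisher's exact test, adjusted p = 0.0241), as did the suberin list (7 higher, 1 lower, 3.11 expected; Fisher's exact test, adjusted p = 0.0355) and the phosphate starvation list (0 higher, 9 lower, 3.39 expected; Fisher's exact test, adjusted p = 0.0172). SAD6 rose from 2.35 to 11.6 FPKM and CYP86A1 from 10.9 to 25.1, while IPS1 fell from 98.1 to 26.7 and PHT1;1 from 202 to 82.4, by the authors' deposited table. The hypoxia call was lost with merged loci left out (Fisher's exact test, adjusted p = 0.158).

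Of the remaining lists in flight Col-0, jasmonate genes were higher in 7 of 7, with JAZ7 rising from 1.09 to 7.67 and JAZ5 from 1.62 to 8.31 FPKM in the authors' deposited table. Photosynthesis genes were lower in 7 of 7 and iron genes in 7 of 8, for example NAS4 from 29.9 to 15.2 FPKM in the authors' deposited table. Nitrate reductase NIA1 rose from 12.5 to 31.4 FPKM while NRT2.1 fell from 2.82 to 0.313 and NRT3.1 from 69.6 to 26.4 in the authors' deposited table. The defence genes ZAT10 and WRKY70 fell from 20.7 to 10.6 and 13.6 to 7.06 FPKM, and the root hair gene RHS19 from 113 to 72.6, by the authors' deposited table. This comparison had 1357 calls, 666 higher and 691 lower, with 435 at 2-fold or more, 245 of these higher.

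In ground Sku6 the rises from 4 to 8 days were led by VSP2 (0.344 to 59.1 FPKM), DIR1 (1.60 to 89.0), the berberine enzyme family gene AT5G44400 (1.25 to 68.6) and the peroxidase gene AT2G18150 (4.71 to 113) in the authors' deposited table. The methyltransferase gene AT1G77520 and AGL19 (AT4G22950) rose 24.1-fold and 21.6-fold in the authors' deposited table. AT5G33330 fell from 943 to 31.9 FPKM, the defensin-like gene AT5G33355 from 719 to 27.2, the invertase inhibitor family gene AT5G46960 from 7.59 to 0.479 and RBCS2B from 13.2 to 0.895 in the authors' deposited table. The hypoxia list had 13 higher and 1 lower member against 7.40 expected (Fisher's exact test, adjusted p = 0.0400), with WIP4 rising from 3.97 to 41.1 FPKM in the authors' deposited table. The suberin list had 8 higher and 1 lower member against 4.28 expected (Fisher's exact test, adjusted p = 0.0490), with GPAT5 rising from 2.57 to 12.2 and CYP86A1 from 11.0 to 45.4 FPKM in the authors' deposited table. Both calls were lost with merged loci left out (Fisher's exact test, adjusted p = 0.0507 and 0.0898). Photosynthesis genes fell in 12 of 12 changed members (exact sign test, adjusted p = 0.0352), with RBCS3B falling from 40.3 to 3.99 FPKM in the authors' deposited table. Their number did not pass (Fisher's exact test, adjusted p = 0.185). The direction was lost with a minimum log2 fold change of 1, which left 8 members, all lower and too few to pass (exact sign test, adjusted p = 0.281).

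Also in ground Sku6, phosphate genes were lower in 8 of 8, iron genes in 8 of 8 and root hair genes in 7 of 7 changed members, without a call for these lists. IRT1 (a merged locus), the main iron transporter gene, fell from 128 to 38.6 FPKM, its regulator FIT from 49.9 to 18.3 and SPX1 from 123 to 45.6, by the authors' deposited table. The wall-loosening list had 7 higher and 5 lower members, including EXPA8 (1.2 to 6.40 FPKM) and XTH21 (97.1 to 47.9), in the authors' deposited table. The camalexin pathway gene CYP71A12 rose from 0.665 to 2.53 FPKM, and the auxin-conjugating gene GH3.2 (a merged locus) from 246 to 561 in the authors' deposited table. Of 1873 calls 946 were higher and 927 lower, while among the 667 at 2-fold or more 441 were higher.

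In flight Sku6, DIR1 (1.91 to 93.1 FPKM), AT4G33720 (2.67 to 99.3), BGLU7 (0.699 to 18.6) and AT5G44400 (1.76 to 36.6) rose most from 4 to 8 days in the authors' deposited table. The decreases were led by ECS1 (37.1 to 1.29 FPKM), MLP28 (44.7 to 2.02), the thioesterase gene AT1G35290 (13.7 to 0.667), LTP4 (10.9 to 0.552), RBCS1B (38.3 to 2.21) and the oleosin-like gene AT5G56100 (29.6 to 1.81) in the authors' deposited table. The hypoxia list had 13 higher and 2 lower members against 6.47 expected (Fisher's exact test, adjusted p = 0.00212), and SAD6 rose from 1.62 to 15.3 and PDC1 from 1.92 to 11.6 FPKM in the authors' deposited table. Photosynthesis genes were lower in 13 of 13 changed members (Fisher's exact test, adjusted p = 0.0355; exact sign test, adjusted p = 0.0264), with RBCS3B falling from 76.9 to 5.45 FPKM in the authors' deposited table. Their direction was lost with a minimum log2 fold change of 1, which left 8 members, all lower and too few to pass (exact sign test, adjusted p = 0.281). RBCS1B, RBCS2B and RBCS3B, markers of shoot tissue, were also higher in 4-day flight Sku6 than in 4-day flight Col-0 and 4-day ground Sku6. Whether shoot tissue on the 4-day roots adds to the fall was not tested. Suberin genes had 9 higher and 1 lower member (Fisher's exact test, adjusted p = 0.00340), with CYP86B1 rising from 2.16 to 9.08 FPKM in the authors' deposited table. Phosphate genes had 9 lower and 0 higher members (Fisher's exact test, adjusted p = 0.0490), with PECP1 falling from 11.0 to 1.05 FPKM in the authors' deposited table. The phosphate call was lost with merged loci left out (Fisher's exact test, adjusted p = 0.0959) and with a minimum log2 fold change of 1 (Fisher's exact test, adjusted p = 0.661). SP1L5, a relative of SPR1, rose from 29.4 to 102 FPKM, NIA1 from 11.5 to 37.8 and the laccase gene LAC4 from 6.14 to 11.7, by the authors' deposited table. The 1647 calls divided into 774 higher and 873 lower loci, with 653 at 2-fold or more, 344 of these higher.

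The age response was shared across place and genotype. Ground and flight shared 692 loci in Col-0, 664 of them with the same direction (2.1 times expected), and 945 loci in Sku6, 925 with the same direction (2.88 times expected). Col-0 and Sku6 shared 924 loci on the ground, 900 with the same direction (2.06 times expected), and 852 in flight, 847 with the same direction (3.64 times expected). The largest adjusted p among these 4 pairs was 2.33e-33 (Fisher's exact test, lower loci of Col-0). DIR1 was higher at 8 days in all 4 comparisons, with log2 values of 5.92 and 5.62 in ground and flight Col-0 and 5.80 and 5.61 in ground and flight Sku6 in the authors' deposited tables.

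Sku6 was compared with Col-0 to see which transcripts differ between the lines. On the ground at 4 days, besides SPR1, the germin-like gene AT5G38940 had a log2 value of −3.76, the TRAF-like gene AT5G26300 −2.5, AT3G04854 −2.12, AT1G43590 −2.11 and AT1G12805 −1.95 in the authors' deposited table. Higher in Sku6 were AT4G10860 of unknown function at 36.8 against 4.08 FPKM and NIMIN1 (AT1G02450), which binds the salicylate regulator NPR1, at 18.4 against 3.01 in the authors' deposited table. The germin-like genes AT5G39130 and AT5G39160 rose 7.40-fold and 5.22-fold, AT1G44010 5.54-fold and DLO1 (AT4G10500), a salicylate hydroxylase gene, 5.28-fold in the authors' deposited table. The xylem and secondary wall list had 5 lower members and none higher, against 0.942 expected (Fisher's exact test, adjusted p = 0.0165). Among them GUX1 was at 0.690 against 1.97, LAC17 at 4.04 against 9.64, LAC4 at 9.88 against 18.5 and the xylem protease gene XCP2 at 36.3 against 54.0 FPKM in the authors' deposited table. With a minimum log2 fold change of 1, 2 members were left and the call was lost (Fisher's exact test, adjusted p = 0.0890). The 5 changed wall-loosening genes and the 3 changed suberin genes were also lower, such as XTH15 (160 against 248 FPKM) and CYP86A1 (10.8 against 27.6), in the authors' deposited table. The flight comparison of 4-day Col-0 contains the same ground Col-0 group. LAC17, LAC4 and CYP86A1 were below that group there too, so the results are not independent of each other. Without that group, xylem genes were 0 higher and 2 lower for Sku6 against Col-0 in flight at 4 days. For flight in 4-day Sku6 they were 1 higher and 2 lower. Whether 4-day ground Col-0 was a displaced group was not tested. There were 573 calls, 283 higher and 290 lower, and 98 reached 2-fold, 47 of these higher.

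In flight at 4 days, the photosynthesis list differed between genotypes more often than expected, with 10 members higher in Sku6 and none lower against 1.52 expected (Fisher's exact test, adjusted p = 3.40e-05). Its direction did not pass (exact sign test, adjusted p = 0.0703), and 301 of all 393 calls in this comparison were higher in Sku6. The Rubisco genes RBCS2B, RBCS3B and RBCS1B were at 34.4 against 11.6, 75.2 against 30.0 and 37.5 against 15.6 FPKM, and the chloroplast dehydrogenase gene GAPB at 25.5 against 11.9, by the authors' deposited table. These genes also mark shoot tissue. The germin-like genes AT5G39160 and GER2 (AT5G39190) rose 9.35-fold and 8.43-fold, the transcription factor gene WRKY59 (AT2G21900) 5.96-fold, AT4G10860 5.46-fold, AT5G42530 4.35-fold and AT2G30670 3.63-fold in the authors' deposited table. Next to SPR1 the lowest were MIR864 at 2.1 against 15.3 FPKM, AT5G18950 at 2.39 against 5.74, the non-coding RNA gene AT3G29644 at 13.3 against 30.2 and UGT74E2, which glycosylates an auxin, at 4.2 against 9.08, by the authors' deposited table. The iron genes BHLH100, COPT2 and FIT were higher at 10.7 against 4.16, 529 against 341 and 43.6 against 28.6 FPKM, and NRT2.1 at 6.70 against 2.72, by the authors' deposited table. Calls numbered 393, with 301 higher and 92 lower in Sku6 and 97 at 2-fold or more, 85 of these higher.

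On the ground at 8 days, the hypoxia and photosynthesis lists differed between genotypes more often than expected. Each had 9 members lower in Sku6 and none higher, against 1.02 expected (Fisher's exact test, adjusted p = 2.10e-05 for each), and the direction passed in neither (exact sign test, adjusted p = 0.0703 for each). SAD6 stood at 4.66 against 24 FPKM, ADH1 at 12.2 against 38.0 and ARD3 at 3.88 against 8.55 in the authors' deposited table. LHCB2.1 was at 5.99 against 13.5, LHCB1.3 at 84.7 against 168 and RBCS1A at 123 against 222 FPKM in the authors' deposited table. The photosynthesis genes also mark shoot tissue, and 13 and 9 of them were called in the 2 comparisons of 8-day groups that contain ground Col-0, against 0 in the 2 that do not. Their call was lost with a minimum log2 fold change of 1, which left 1 member (Fisher's exact test, adjusted p = 0.775). The late embryogenesis abundant gene AT3G02480 rose 16-fold in Sku6, AT5G55620 9.19-fold, MIR160b 6.03-fold, AT5G04120 5.57-fold, MRN1 5.19-fold and AT2G16005 3.93-fold in the authors' deposited table. AT4G33720 was at 7.60 against 49.1 FPKM, AT5G38940 at 5.76 against 32.1 and the amino acid export gene GDU5 (AT5G24920) at 2.61 against 8.24 in the authors' deposited table. The phosphate genes RNS1, AT4 and SPX1 were higher, with log2 values of 1.41, 0.82 and 0.53 in the authors' deposited table. This comparison had 266 calls, 145 higher and 121 lower, of which 83 reached 2-fold, 55 of these higher.

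In flight at 8 days, the hypoxia list differed between genotypes more often than expected, with 7 members higher in Sku6 and none lower against 1.09 expected (Fisher's exact test, adjusted p = 0.00165). The direction of this list did not pass (exact sign test, adjusted p = 0.153), and 206 of all 280 calls in this comparison were higher in Sku6. PDC1 stood at 12.1 against 5.22 FPKM, HUP36 at 35.7 against 16.4 and ADH1 at 26.7 against 14.7 in the authors' deposited table. With a minimum log2 fold change of 1, 2 members were left and the call was lost (Fisher's exact test, adjusted p = 0.0759). The copper transport family gene AT5G52670 rose 8.62-fold, MIR864 5.17-fold, AT1G73120 5.14-fold, AT3G02480 3.22-fold, NIMIN1 3.05-fold and AT5G35935 2.97-fold in the authors' deposited table. AT1G43590 was at 2.91 against 38.5 FPKM, MIR160b at 3.16 against 12.4, AT3G29644 at 18.7 against 52.5 and the jasmonate repressor gene JAZ5 at 3.08 against 8.5, by the authors' deposited table. In total 280 loci were called, 206 higher and 74 lower, with 34 at 2-fold or more, 26 of these higher.

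**Figure D3:**
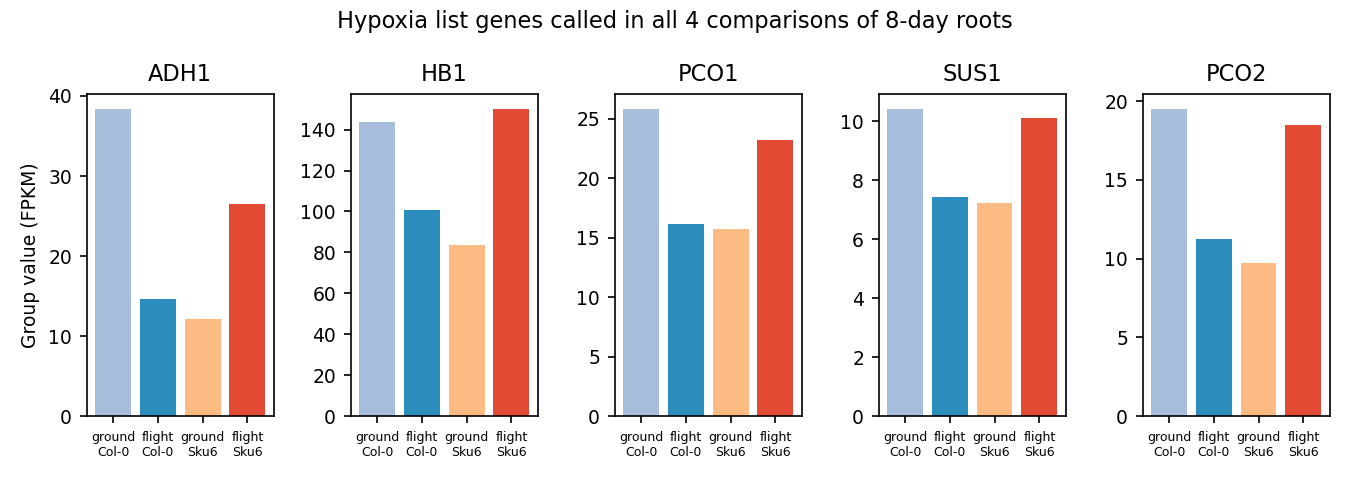
FPKM of 5 hypoxia list genes in the 4 groups of 8-day roots, each bar the group value in the authors' deposited flight tables (1 table per genotype, scaled separately), with no error bars because no values per sample were in hand. PCO2 belongs to a merged locus. In each gene ground Col-0 lies above flight Col-0 and flight Sku6 above ground Sku6, for ADH1 38.4 against 14.7 and 26.5 against 12.2 FPKM.

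The genotype lists overlapped more than independent lists would. Ground and flight shared 94 loci at 4 days, 92 with the same direction (3.95 times expected), and 52 at 8 days, 40 with the same direction (4.95 times expected). The ages shared 67 loci on the ground, 58 with the same direction (3.66 times expected), and 93 in flight, 87 with the same direction (6.07 times expected). The largest adjusted p of these 4 pairs was 0.000483 (Fisher's exact test, lower loci at 8 days). NIMIN1 was higher in Sku6 in each of the 4 comparisons, with log2 values of 2.61, 1.54, 1.65 and 1.61 on the ground and in flight at 4 days and then at 8 days in the authors' deposited tables. DLO1 followed the same direction with 2.4, 1.63, 1.65 and 1.48, and ALD1 (AT2G13810), which takes part in making the defence signal pipecolate, with 2.1, 2.32, 1.42 and 1.69 on the log2 scale of the authors' deposited tables.

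**Figure D4:**
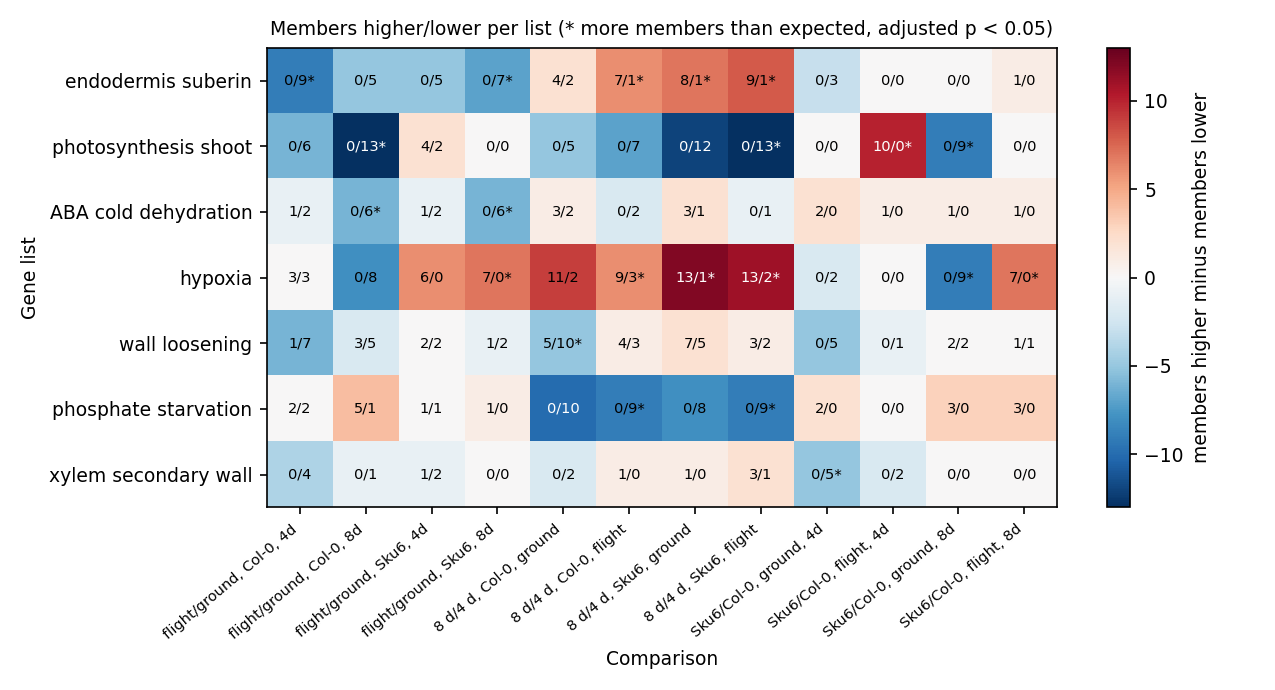
Changed members higher/lower for the 7 fixed lists (vertical axis) called in at least 1 of the 12 comparisons (horizontal axis) of the authors' deposited tables. Colour gives higher minus lower members, and an asterisk marks an adjusted p under 0.05 in Fisher's exact test, for example 10 higher and 0 lower photosynthesis genes for Sku6 against Col-0 in flight at 4 days.

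Over the 18 fixed lists and 12 comparisons, 21 tests passed, all with more changed members than expected. The exact sign test of direction passed in 3 cases, all of lower photosynthesis genes (8-day Col-0 in flight against ground, and 8 against 4 days in Sku6 on the ground and in flight). In the Col-0 case, 560 of all 812 calls were lower. For the other lists the directions are counts of changed members only. No list with 10 or fewer changed members could pass, so a direction that did not pass is not shown to be mixed. Against the background of listed genes, the lists of microtubules, root hairs, heat shock, defence, jasmonate, auxin, iron, nitrate and sulfur, the cell cycle and the circadian clock passed in no comparison. That background holds only genes called in some comparison, and wider ones gave more list calls. These lists are therefore not shown to be unchanged. Only 3 of 23 cell cycle genes, 7 heat shock genes, 7 clock genes and 8 defence genes were in the background, so those lists had little power. No member of the seed storage list was listed in any of the authors' deposited tables.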

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

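The tests of the hypoxia pattern below were chosen after the result was seen, while the overlap that produced the gene differences was planned. The changed hypoxia genes of 8-day roots lay in opposite directions in flight in the 2 genotypes, with 0 higher and 8 lower in Col-0 and 7 higher and 0 lower in Sku6 (Fisher's exact test of the difference, adjusted p = 0.0112). The same groups read the other way gave 0 higher and 9 lower for Sku6 against Col-0 on the ground and 7 higher and 0 lower in flight (Fisher's exact test, adjusted p = 0.0112). These genes are not independent of each other, and at least 5 of them stand in both counts of each test. The tests compare counts of called genes and are not tests of a flight response that depends on genotype. They also leave out of account the direction of all calls. For flight, 252 of 812 were higher in Col-0 and 214 of 496 in Sku6. For Sku6 against Col-0, 145 of 266 were higher on the ground and 206 of 280 in flight.

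An exchange of the flight and ground labels of 8-day Sku6 is argued against, since it would turn most shared loci to opposite directions, and 14 of 201 (6.97%) were. Genotype labels exchanged for 1 or more libraries would bring the abundant SPR1 transcript into Sku6, and the higher Sku6 level at 8 days was 0.912% of its Col-0 partner in the authors' deposited tables. A single displaced group among the 4 groups of 8 days would leave the comparisons without it uncalled, but 5 members (ADH1, HB1, PCO1, SUS1 and the merged locus of PCO2, named here after their values were seen) were called in all 4 comparisons. A candidate explanation left open is that at least 2 of the groups differed in oxygen supply or handling, and another is a flight response that depends on genotype. Neither was tested, because no value per dish or sample was in hand.

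Other differences are given as values. In each case both of the authors' deposited tables called the gene in opposite directions, and the difference itself was not tested, for lack of values per sample. Numbers are differences of the deposited log2 fold changes, first minus second, and a pair of values recurs where the same 4 groups were read both ways. For flight in Col-0 minus Sku6 at 4 days, they were −3.65 for the transporter gene AT5G46040, 1.73 for RTFL15, −1.22 for GAPB and −0.89 for the peroxidase gene AT5G64100 in the authors' deposited tables. At 8 days the same difference was 4.56 for MIR160b, −3.21 for AT1G12805, −2.51 for ADH1 and −2.77 for SAD6 in the authors' deposited tables. For flight at 4 minus 8 days in Col-0, MRN1 gave −2.23, the transporter gene UMAMIT14 −1.64, CYP82F1 −1.40 and AT2G42110 1.31 in the authors' deposited tables. In Sku6 that difference was 4.47 for MIR160b, 3.79 for BCB, a blue copper protein gene, 1.79 for AT5G38020 and −1.13 for the protease gene DEG14 in the authors' deposited tables.

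For the age response on the ground minus in flight in Col-0, AT5G66390 gave −1.80, AT3G18773 1.44, AT2G39430 −1.90 and UMAMIT14 −1.64 in the authors' deposited tables. In Sku6 the values were 4.47 for MIR160b, 2.99 for the peroxidase gene PRX52, 2.76 for CCL and 3.80 for BCB in the authors' deposited tables. The age response of Col-0 minus Sku6 on the ground differed by −4.57 for CYP71A12, −3.40 for AT3G02480, −2.64 for the sugar transporter gene SWEET11 and 2.19 for AT1G47405 in the authors' deposited tables. In flight it differed by −5.23 for MIR864, −2.31 for AT5G35935, −1.49 for AT2G07739 and −0.78 for AT3G12965 in the authors' deposited tables.

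For Sku6 against Col-0, ground minus flight at 4 days was 1.73 for RTFL15 and 0.79 for AT3G12965, the 2 loci with opposite calls, in the authors' deposited tables. At 8 days it was 4.56 for MIR160b, −3.21 for AT1G12805, −2.50 for ADH1 and −1.97 for PDC1 in the authors' deposited tables. The genotype difference at 4 minus 8 days on the ground was −2.43 for AT3G29410, −1.50 for AT2G26690, −1.50 for AT1G55990 and 1.48 for AT3G59930 in the authors' deposited tables. In flight it was −5.24 for MIR864, −1.49 for AT2G07739, −1.15 for the thioredoxin gene TH7 and −1.15 for DEG14 in the authors' deposited tables.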

How the results depend on the processing

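Chosen after the results were seen were the background of loci tested and the exclusion of merged loci or loci without an identifier. In this paragraph counts run in a fixed order, flight against ground (Col-0 4 and 8 days, Sku6 4 and 8 days), age (Col-0 ground and flight, Sku6 ground and flight) and Sku6 against Col-0 (ground and flight at 4 days, ground and flight at 8 days). At a q-value of 0.01 the counts of changed loci were 752, 509, 532, 313, 1418, 819, 1196, 1061, 302, 219, 163 and 133. With an absolute log2 fold change of at least 1 they were 276, 103, 367, 111, 578, 435, 667, 653, 98, 97, 83 and 34, and with 1 FPKM added to both groups first 208, 74, 309, 84, 425, 344, 531, 525, 74, 81, 66 and 29. Stricter limits keep fewer loci by construction. With minimum values of 1 or 5 FPKM, without values of 0 and without merged or unnamed loci, each of the 12 counts stayed within 1.5 times the reported one.

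All 12 overlaps kept both directions past the threshold under the 6 alternatives run for them. Of the 21 list calls, 21 held with either wider background, 12 with a log2 fold change of at least 1 and 15 with merged loci left out, and 9 held under all 4. The number of list calls rose to 67 with the protein-coding genes of the reference as background and to 51 with the number of loci tested, since a wider background lowers the number of members expected by chance. The 3 calls of the sign test became 0 with a log2 fold change of at least 1. That left 4, 8 and 8 members, all lower and too few to pass. With 1 FPKM added to both groups, which cannot turn a direction, 78 fold changes of named genes shrank by more than 1.5 times and 498 by less.

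Each of the 78 had a group under 2 FPKM. For flight against ground they were SEN1, AT1G49570, MIR864 and AT5G46040 in Col-0 at 4 days, AT5G55620, RR17, LHCB2.2, PRR9 and AT1G49570 in Col-0 at 8 days, SEN1, AT1G49570, AT5G46040 and BCB in Sku6 at 4 days, and AT1G49570, MIR864 and EPR1 in Sku6 at 8 days. For age they were VSP2, AT2G26695, AT2G04460, ECS1, RBCS2B, AT3G44970, MLP168, RBCS1B, CYP71A12, GH3.1 and NRT2.1 in ground Col-0, and DIR1, VSP2, BGLU7, ECS1, AT1G73120, SEN1, LTP, RBCS1B, JAZ7, RBCS2B, LHCB2.2 and NRT2.1 in flight Col-0. In ground Sku6 they were VSP2, DIR1, AT5G44400, AT1G77520, AGL19, AT5G46960, RBCS2B, ECS1, RBCS1B, EXPA8, CYP71A12, JAZ5, GH3.1, NRT2.1, PRX52 and BCB, and in flight Sku6 DIR1, BGLU7, AT5G44400, ECS1, AT1G35290, LTP4, AT5G56100, SAD6, LHCB2.2, PECP1 and NRT2.1. For Sku6 against Col-0 they were AT5G39130, AT1G44010, AT5G26300, GUX1 and CYP71B9 on the ground at 4 days, AT5G39160, WRKY59 and ALD1 in flight at 4 days, AT5G55620 and CYP71B9 on the ground at 8 days, and AT5G52670 and ALD1 in flight at 8 days.

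No paired analysis was possible because the authors' deposited tables hold pooled group values and the replicate numbers carry no values. For the same reason the fit with a replicate block, leaving out each replicate in turn, other splits of the samples and limma with a pseudocount of 0.1 were not run. Sequencing depth was unknown, so no limit from counts can be set on low values.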

Other observations

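The lists and tests of this part were all chosen after results had been seen, so their p-values are not independent evidence. The genes named in this part were likewise chosen after their values were seen, outside the fixed naming rule unless the report names them too.

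Of 19 members of a list of light-responsive and flavonoid genes, 13 were lower in Col-0 at 4 days, 8 in Col-0 at 8 days, 13 in Sku6 at 4 days and 9 in Sku6 at 8 days, with none higher (Fisher's exact test, adjusted p = 1.38e-05, 0.00288, 6.95e-08 and 1.38e-05). In Col-0 at 4 days, chalcone synthase (CHS) stood at 628 FPKM in flight against 1065, flavonol synthase (FLS1) at 183 against 335, the flavonol regulator MYB12 at 25.7 against 87.3 and the light-signalling factor HY5 at 44.5 against 65.0, by the authors' deposited table. Of the flavonoid enzyme genes CHS, CHI, F3H and FLS1, all lower at 4 days in both genotypes, none was called at 8 days in Col-0 and only F3H in Sku6 (log2 of −0.42), so the 8-day calls were mainly of light-responsive genes and regulators such as HY5 and MYB12 in the authors' deposited tables. As a hypothesis, light-responsive transcripts may be lower in flight at both ages and those of flavonoid enzymes at 4 days. Enzyme genes not listed at 8 days are not shown to be unchanged, and no difference between the ages was tested. Among the members whose values had not been seen when the list was written, 23 of 23 calls (100%) in 8 genes were lower. They include calls of HYH, a merged locus, at 4 days in each genotype. Whether light at the root, another cue or the 48-h offset of the ground set underlies this was not tested.

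A list of 19 low-energy genes, which are known to rise when sugar is short, had 6 higher members in Col-0 flight roots of 4 days and 10 in Sku6 flight roots of 4 days, with none lower (Fisher's exact test, adjusted p = 0.208 and 5.03e-06). In flight, 9 members were lower at 8 than at 4 days in each genotype (Fisher's exact test, adjusted p = 0.00155 in Col-0 and 0.00531 in Sku6). On the ground, 2 were lower and 0 higher in Col-0 (Fisher's exact test, adjusted p = 0.178). In ground Sku6, 0 changed, fewer than the 4.28 expected (Fisher's exact test, adjusted p = 0.0274). The background holds only genes called in some comparison, and 11 of the 19 members were in it, some through the flight comparisons. A count below the expected one on the ground is thus partly built in and does not show a lack of change. The falls with age in flight use the same 4-day flight groups in which members had been seen higher, so they are not separate support. The hypothesis that low-energy transcripts may be higher in both genotypes in flight at 4 days stays open. The calls of members not seen before were higher in 5 of 5 cases (100%), but all 5 were in Sku6 (AT3G15450, TPS10, PRODH1, BGAL4 and AKINBETA1) and none in Col-0 at that age. At 8 days each genotype had 4 members higher in flight and none lower (Fisher's exact test, adjusted p = 0.208 in Col-0 and 0.0566 in Sku6), among them AT3G15450 and BGAL4 in Col-0 at 145 against 68.5 and 10.8 against 6.22 FPKM in the authors' deposited table.

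A list of salicylate-linked genes differed between genotypes more often than expected. Of 28 members, 6 were higher in Sku6 on the ground and 7 in flight at 4 days and 5 in each place at 8 days, with none lower (Fisher's exact test, adjusted p = 0.00462, 8.11e-05, 0.00153 and 0.00155). The direction passed in none (exact sign test, adjusted p = 0.102, 0.0703, 0.173 and 0.173), which was bound to happen with 7 or fewer changed members. Of all calls, 301 of 393 and 206 of 280 were higher in Sku6 in flight at 4 and 8 days, against 283 of 573 and 145 of 266 on the ground. The directions in flight thus partly reflect that skew. When the list was written, 13 of its members had been seen, among them NIMIN1, DLO1, ALD1, NPR3, DMR6, WRKY59 and WRKY70, and the hypothesis that salicylate-linked transcripts may be higher in Sku6 stays open. Every called member except the glutaredoxin gene GRXS13 was thus known beforehand, and its 2 calls, both higher, are too few to decide.

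The changed photosynthesis genes of 8-day roots were all lower in flight Col-0 and in ground Sku6 than in ground Col-0. A single displaced group, the 8-day ground Col-0 roots, goes with the counts at 8 days, since 13 and 9 members were called in the 2 comparisons with that group and 0 in the 2 without it. In 4-day Col-0, a comparison without that group, 6 members were also lower in flight and 0 higher, against 5.6 expected. Lower calls in flight Col-0 are thus not confined to comparisons with 8-day ground Col-0. Whether shoot tissue was left on the 8-day ground Col-0 roots could not be told from other Rubisco genes, of which 1 of 3 reached 5 FPKM in any of the groups named next. In ground Col-0, flight Col-0 and ground Sku6, RBCS3B was at 7.09, 4.70 and 3.99 FPKM, on the side of shoot tissue, and RBCS1B at 1.27, 1.45 and 1.61 and RBCS2B at 0.636, 1.28 and 0.895 FPKM were not, in the authors' deposited tables, which were scaled separately. What set 8-day ground Col-0 apart, in handling or in the biology of its roots, was not tested, and no leaf profile was in hand. The same marker check was not made for 4-day flight Sku6. There RBCS1B, RBCS2B and RBCS3B were at 37.5, 34.4 and 75.2 FPKM against 15.6, 11.6 and 30.0 in 4-day flight Col-0. Against 4-day ground Sku6 they were higher too, but the photosynthesis list split into 4 higher and 2 lower members.

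Outside SPR1, 59 loci lay on the same side in at least 3 of the 4 genotype comparisons, 52 higher and 7 lower in Sku6. Of all calls, 301 of 393 and 206 of 280 were higher in Sku6 in flight at 4 and 8 days, against 283 of 573 and 145 of 266 on the ground. Sequence differences linked to the sku6 allele could account for some of the 59 loci, since 5 of the 59 (8.47%) lay within 2 Mb of SPR1, against 93 of 4742 other listed loci (1.96%; 1-sided Fisher's exact test, p = 0.00670). The 5 are AT2G01530, AT2G01670, AT2G01900, CYP71B9 and AT2G05995, the last listed at 0 FPKM in Sku6 in 3 of the authors' deposited tables. The other 54 lie elsewhere in the genome, and for them an effect of the allele and differences in other parts of the genome stay open and untested. Values of 0 are not confined to the region of SPR1. A merged locus on chromosome 3 (AT3G42900, AT3G42913 and AT3G42927) was at 0 FPKM in Col-0 in 4 comparisons. An unnamed locus on chromosome 2 (6439960 to 6440750) was at 0 in Sku6 in 3.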
